A study of Mus musculus with 30 samples.

How the data were processed

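The series holds 30 mouse samples, of which 18 are RNA-seq libraries of splenic B cells and all 18 were analysed. The remaining 12 are chromatin assays and were not analysed here. For 3 of those 12 the sample title and the genotype field disagree, so they were put in no group. The RNA-seq libraries fall into 5 groups: B cells of young wild-type mice (n = 3) and of young mice homozygous for an Ikzf3 missense mutation restricted to B cells (n = 3), and, from aged mice, wild-type B cells (n = 3), B cells other than the leukaemic clone of mutant mice (non-CLL B cells, n = 4) and CLL-like cells of mutant mice (CLL cells, n = 5). Per the labels, CLL cells and non-CLL B cells numbered 2, 4 and 5 come from heterozygous mice and those numbered 6 from a homozygous mouse, and CLL library 1 is heterozygous and has no non-CLL partner. Per the labels, B cells were isolated from the spleen with magnetic beads after lysis of red cells, at a purity of at least 85% in the aged series, and CLL cells were sorted by flow cytometry for B220 and CD5. The aged libraries carry numbers. For the young libraries the labels do not state that each comes from a separate animal.

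Both expression tables hold TPM (transcript abundance scaled by gene length and library size) computed by the authors: the labels of the aged samples name the unit, and the values of every library of either table add up to the full scale of the unit. Reads were handled with mm10 as reference and with STAR 2.4.0.1, Bowtie2 2.3.4.1 and MACS2 2.2.0, per the submitters' processing notes, which do not say which tool was used for which assay. The quantification tool, the annotation, the library strandedness and any filter on genes are not given in the sources used here. TPM values keep no record of the number of reads, so the depth of each library is unknown and no counting interval can be given. Because the deposited TPM values are not counts, limma was used for the young comparison in place of the count-based test chosen before the data were examined. The deposited lists hold 22806 genes in the aged and 27179 entries in the young table. Left out were 25 and 26 genes whose names a spreadsheet had turned into dates, and 887 entries of the young table with no gene name, which hold between 4.44% and 9.36% of TPM per library. This left 22781 and 26266 genes, 20768 of them shared by symbol. The aged table lists no immunoglobulin, T cell receptor or mitochondrial genes, and genes with many processed copies are listed far lower in it than in the young table (Gapdh has a mean of 16.1 TPM in the aged and 629 TPM in the young table), so every test was made within 1 table. Of the symbols, 20356 in the aged and 25054 in the young table were found in the RefSeq gene table of GRCm38.p6 (the assembly of mm10), which gave the coordinates printed.

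For each comparison, genes with at least 1 TPM in as many libraries as the smaller group has were kept, values were taken as log2(TPM + 1), and groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a trend in the variance and robust estimation, two-sided). P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. Fold values are the log2 change turned into a ratio on this scale, and SE is the standard error of the log2 change. The comparisons were young homozygous against young wild-type B cells, aged CLL cells against aged wild-type B cells, aged CLL cells against aged non-CLL B cells, and aged non-CLL B cells against aged wild-type B cells. The procedure was tested on simulated data with 100 genes changed by each size. At a log2 change of 2 it recovered 98% of changed genes in the young comparison, 77% for CLL cells against wild-type, 80% for CLL cells against non-CLL B cells and 60% for non-CLL B cells against wild-type. At a log2 change of 1 the recovered shares were 92%, 4%, 20% and 3%. False calls made up between 3.08% and 4.76% of calls. The simulated values held no background signal and no correlation between genes, and only genes with a mean over about 20 TPM were changed. These shares are therefore no error rate for the real calls in the aged table, many of which lie under 20 TPM.

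Before the data were examined, 27 gene lists were fixed, covering B cell receptor signalling and its inhibition, immediate early genes, NF-kB targets, B cell subsets, transcription factors, human CLL genes, metabolism, heat shock and markers of other spleen cells. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, which asks whether a list moves more than all other genes, and with an estimated correlation. They were also tested with fry, which asks whether a list's genes move on balance in 1 direction and makes no comparison with other genes. The genes named were fixed by rule: Ikzf3, the sort markers Cd5 and Ptprc (which encodes B220), the 8 largest log2 changes per direction among called genes whose groups do not overlap and whose mean is at least 5 TPM in the higher group, leaving out immunoglobulin and T cell receptor segments and gene models without a name of their own, and up to 4 called members per list with the smallest adjusted p. Not every gene that the rule selects is named in the text. Genes named outside this rule are said to be chosen after their values were seen.

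The series' description takes the non-CLL cells from the mice that gave the CLL cells, and libraries of both groups that share a number also share a genotype. Libraries numbered alike were therefore read as those of 1 mouse, although no label names the animal, and a fit with mouse as a block over mice 2, 4, 5 and 6 was made beside the unblocked one. Residual correlations do not show the pairing by themselves: between the 2 libraries of a number they were -0.02, -0.01, 0.06 and 0.21 for mice 2, 4, 5 and 6 over 6782 genes. In the young table they were -0.05, 0.28 and 0.33 for the numbers 1, 2 and 3, and library 1 correlated best with another number, so the numbers were not taken as pairs. Alternatives were other pseudocounts (0.1 and, in the aged table, 5), no filter, TMM rescaling, library weights, a fit of all 12 aged libraries, blocks, and leaving out each library in turn. Chosen only after the data were seen were a minimum mean of 20 TPM in either group, subtraction of a background, TMM rescaling and rescaling without immunoglobulin genes for the young table, and leaving out the young wild-type libraries 1 and 2. The background of a library is its median TPM over 1084 olfactory receptor genes, which B cells are not known to express. It was subtracted from every gene before rescaling, together with the minimum of 20 TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.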

Results

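Gene expression was measured by RNA-seq in splenic B cells of mice that carry an Ikzf3 missense mutation in B cells only, and of wild-type mice, at 2 to 3 months (young) and at 15 to 18 months of age. Ikzf3 encodes Aiolos, a zinc finger transcription factor of B cells. The young set holds 3 homozygous and 3 wild-type libraries. The aged set holds 5 libraries of CLL cells (CD5-positive, CLL-like), 4 of non-CLL B cells of mutant mice and 3 of wild-type B cells. All values are TPM, so the depth behind each is unknown.

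Ikzf3 (chromosome 11, 98464610 to 98546031 in mm10) was at 413 ± 29.6 TPM (SD, n = 3) in young homozygous and 246 ± 31.2 TPM (n = 3) in young wild-type B cells, a log2 change of 0.75 (SE 0.11, adjusted p = 0.000869). In the aged set it was at 688 ± 325 TPM in CLL cells (n = 5), 511 ± 122 TPM in non-CLL B cells (n = 4) and 601 ± 289 TPM in wild-type B cells (n = 3). No call was made between these groups. The log2 change was 0.14 (SE 0.39, adjusted p = 0.804) for CLL cells against wild-type, 0.31 (SE 0.33, adjusted p = 0.486) for CLL against non-CLL cells and -0.17 (SE 0.32, adjusted p = 0.689) for non-CLL B cells against wild-type. The mutation is a missense change, so these levels do not check the genotype labels. With TMM rescaling the change for CLL cells against wild-type turned to -0.28. For non-CLL B cells it was 0.23 with library weights and, then called, -1.32 with TMM rescaling. Cd5, the marker by which CLL cells were sorted, was at 22.0 ± 8.45 TPM in CLL cells, 8.56 ± 2.57 TPM in non-CLL B cells and 0.725 ± 0.401 TPM in aged wild-type B cells. It was called higher than in wild-type cells both in CLL cells (adjusted p = 6.53e-06) and in non-CLL B cells (adjusted p = 0.000127). In the non-CLL libraries its level equals the background, taken as the median of olfactory receptor genes (8.25 ± 0.854 TPM, against 0.248 ± 0.430 TPM in wild-type B cells), and it lies under a minimum of 20 TPM. Between CLL and non-CLL cells its log2 change was 1.24 (SE 0.39, adjusted p = 0.0518).

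The first comparison asks what the mutation changes in B cells before any leukaemia. In young homozygous B cells 20 of 25 immediate early genes, which activated lymphocytes transcribe within minutes, were called higher (adjusted p = 0.535 for the list with an estimated correlation). Fosb (chromosome 7, 19302696 to 19310118) stood at 453 ± 52.0 TPM against 27.1 ± 11.1 in wild-type (17.1-fold, log2 4.09, SE 0.33, adjusted p = 0.000734). The activation marker Cd69 stood at 432 ± 20.3 against 64.5 ± 5.49 TPM (log2 2.73, SE 0.09, adjusted p = 9.33e-07). Nr4a1, a nuclear receptor induced by antigen receptor signals, was at 302 ± 34.9 against 50.1 ± 7.13 TPM (adjusted p = 5.16e-06), and Jun at 532 ± 34.2 against 128 ± 20.9 TPM (adjusted p = 1.89e-05). Myc rose by a log2 change of 1.69 (adjusted p = 1.45e-05). Heat shock genes were called higher in 11 of 12 cases (adjusted p = 0.535 for the list with an estimated correlation), led by the chaperone Hsph1 at 313 ± 9.77 against 27.9 ± 1.89 TPM (10.9-fold, log2 3.44, SE 0.08, adjusted p = 1.19e-07). Hsp90aa1 was at 673 against 211 ± 11.3 TPM (adjusted p = 4.01e-06). Other large increases were Gla, a lysosomal galactosidase (log2 3.32, adjusted p = 1.43e-06), and the transcription factors Klf4 (log2 2.79, adjusted p = 0.000732) and Atf3 (log2 2.99, SE 0.71, adjusted p = 0.0234). The precursor genes Mir23a, Mir27a and Mir24-2, a microRNA cluster on chromosome 8, rose by 3.60, 2.84 and 4.33 on the log2 scale (adjusted p = 9.1e-06, 0.000997 and 7.33e-05). Their strand and overlap with longer transcripts are not resolved here. Atf3 lost its call without wild-type library 1 (adjusted p = 0.0662), homozygous library 1 (0.0522) or homozygous library 2 (0.0818). Cd5 was at 3.44 ± 0.257 and 3.27 ± 0.414 TPM (log2 0.06, adjusted p = 0.736), and Ptprc rose (log2 0.58, adjusted p = 0.00145).

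Among the largest decreases were genes of neutrophils and macrophages. S100a9 stood at 51.2 ± 29.9 TPM in homozygous and 846 ± 528 TPM in wild-type libraries (log2 -4.03, SE 0.68, adjusted p = 0.00859). S100a8 was at 36.6 ± 23.5 and 546 ± 350 TPM (log2 -3.94, SE 0.77, adjusted p = 0.0137). Retnlg, Hp, Wfdc17, S100a6, Saa3 and Ccl6 had log2 changes between -3.80 and -3.02 (adjusted p between 0.00286 and 0.0443). Of 22 myeloid markers 6 were lower and 0 higher (adjusted over the list alone, 3 and 0), with Csf3r at log2 -2.56 (adjusted p = 0.0309) and Marco at -1.96 (adjusted p = 0.00431). The list's median log2 change was -1.52 (camera, adjusted p = 5.72e-09). T cell markers were lower in 4 of 15 cases (3 adjusted over the list alone, camera adjusted p = 8.69e-05), among them Cd4 (log2 -1.24, adjusted p = 0.000772) and Cd3g (log2 -1.62, adjusted p = 0.00512). NK and dendritic cell markers were lower in 3 of 14 (2 adjusted over the list alone, camera adjusted p = 0.00071). All 3 list calls were lost (adjusted p = 0.629 with an estimated correlation). Lyz2, an abundant macrophage transcript, was at 1443, 2330 and 222 TPM in wild-type libraries 1, 2 and 3 and between 58.2 and 163 TPM in the homozygous libraries. With wild-type libraries 1 and 2 left out, a setting chosen after the data were seen, S100a9, S100a8, Retnlg, Ccl6 and Csf3r were no longer called. Leaving out any 1 library except wild-type 3 ended the call of Ccl6 (adjusted p between 0.0569 and 0.132). Csf3r lost its call without wild-type 1 (0.0887), wild-type 2 (0.0639), homozygous 2 (0.0860) or homozygous 3 (0.0795), and Saa3 without wild-type 2 (0.0649) or homozygous 2 (0.0685). Hp lost it without wild-type 1 (0.05002) and Retnlg without homozygous 2 (0.0540).

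Among gene lists of B cell function, 20 of 25 immediate early genes were higher and 0 lower (the same adjusted over the list alone), with a median log2 change of 1.45 (camera adjusted p = 5.03e-05). Heat shock genes were higher in 11 of 12 cases (12 adjusted over the list alone), also with a median of 1.45 (camera adjusted p = 4.55e-05), and included Dnajb1 (log2 1.5) and Hspd1 (log2 0.95). Both calls were lost with an estimated correlation (adjusted p = 0.535 with an estimated correlation for each). Fry, which asks only whether genes move in 1 direction, gave adjusted p = 0.00057 and 0.000204. Genes of B cell receptor signalling were higher in 20 of 30 cases and lower in 1 (20 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0181). Among them were the kinase Syk (log2 0.57), the calcium channel Itpr2 (0.66) and Nfatc1 (0.51). Of 24 Ikaros family and B cell transcription factors 17 were higher and 0 lower (17 and 1 adjusted over the list alone, camera adjusted p = 0.00926). They included Irf4 (log2 1.53, adjusted p = 2.93e-05), Bach2, a repressor of plasma cell genes (0.98), Foxo1 (0.82) and Bcl11a (0.79). Follicular B cell markers rose in 14 of 18 cases and fell in 2 (the same adjusted over the list alone, camera adjusted p = 0.0337). Klf2, a regulator of lymphocyte trafficking, was at log2 1.38, Ccr7 at 0.58 and Cxcr5 at -0.73. Of B-1 cell markers 9 of 20 were lower and 2 higher (11 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 5.21e-05). Nid1 (log2 -1.29), Vim (-1.02) and Hopx (-0.64) were lower and the inhibitory receptor Ctla4 (2.23) higher. The B-1 list also holds S100a6, named above among the decreases with myeloid genes. S100a6 and Vim were highest in wild-type library 2 (163 and 222 TPM), as were Lyz2 and S100a8. For the list as a whole, a change of B-1 cells therefore cannot be told apart from one in myeloid RNA here. This limit rests on S100a6 and Vim. Nid1 (8.98 to 9.29 TPM) and Hopx (25.5 to 30.0 TPM) varied far less among the wild-type libraries than Lyz2 (222 to 2330 TPM). Of marginal zone markers 8 of 19 were lower and 5 higher (the same adjusted over the list alone, camera adjusted p = 0.0106), with Ccdc28b at log2 -1.48, Dtx1 at -0.62, Plac8 at -0.53 and Notch2 at 0.61. Interferon response genes were lower in 7 and higher in 3 of 25 cases (the same adjusted over the list alone, camera adjusted p = 0.00255), with Ifi27l2a at log2 -1.13 and Stat2 at 0.53. Apart from the immediate early and heat shock lists, these calls were lost too (adjusted p = 0.629 with an estimated correlation). With at least 20 TPM, a minimum chosen after the data were seen, camera called the immediate early (adjusted p = 4.4e-05), heat shock (0.000447), B-1 (0.000397), marginal zone (0.0203), myeloid (3.95e-08) and glycolysis (0.00387) lists, and each of these calls was lost (adjusted p between 0.262 and 0.692 with an estimated correlation).

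The remaining lists of the young comparison are given with the counts adjusted over the list alone in brackets. NF-kB targets were higher in 15 and lower in 2 of 31 cases (15 and 2, camera adjusted p = 0.126). Nfkbid (log2 2.35), Nfkbiz (2.14) and the inhibitor Tnfaip3 (1.21) were higher and the cytokine subunit Ebi3 (-1.63) lower. BCL2 family genes were higher in 5 and lower in 3 of 14 (5 and 3, adjusted p = 0.517), with the pro-apoptotic Pmaip1 (log2 2.196) and the anti-apoptotic Bcl2 (0.59) higher and Bak1 (-0.51) lower. Inhibitors of B cell receptor signalling were higher in 8 and lower in 6 of 25 (8 and 6), with Cbl (log2 1.37) and Siglecg (0.75) higher. Their median was 0.11 while camera pointed down (adjusted p = 0.370), against a median of all genes of 0.18. Human CLL-associated genes were higher in 8 and lower in 1 of 17 (8 and 1, adjusted p = 0.486), including Cd274, the ligand of PD-1 (log2 0.92), and Fcer2a, which encodes CD23 (0.75). Homing genes were higher in 4 and lower in 6 of 22 (3 and 6, adjusted p = 0.0337), with the chemokine receptor Cxcr4 at log2 1.51. Cell cycle genes were higher in 2 and lower in 4 of 31 (0 and 2, adjusted p = 0.0181), and glycolysis genes higher in 1 and lower in 3 of 16 (1 and 3, adjusted p = 0.00574). The homing, cell cycle and glycolysis calls were lost (adjusted p = 0.629 with an estimated correlation). Camera called none of the lists that follow, and fry called only precursor B cell genes among them, up (adjusted p = 0.00736). Precursor B cell genes were higher in 5 and lower in 1 of 8 cases (5 and 1, camera adjusted p = 0.433), germinal centre markers in 3 and 2 of 16 (3 and 0, adjusted p = 0.120) and plasma cell markers in 4 and 2 of 20 (4 and 2, adjusted p = 0.239). Antigen presentation genes were higher in 3 and lower in 2 of 19 (2 and 1, adjusted p = 0.126), and Toll-like receptor signalling genes in 5 and 5 of 20 (5 and 5, adjusted p = 0.123). Erythroid markers had 0 and 0 of 15 (0 and 0, adjusted p = 0.120), immunoglobulin constant regions 1 and 1 of 11 (0 and 0, adjusted p = 0.126) and sex-linked genes 0 and 0 of 4 (0 and 0, adjusted p = 0.201). The stromal list had 1 tested gene, not called.

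In all, limma called 4698 genes higher and 1539 lower of 12219 tested, so 75.3% of called genes were higher. Groups did not overlap for 7499 genes (61.4%, against 10% by chance). TMM rescaling moved the median log2 change of all genes from 0.18 to 0.000486 and gave 2859 higher and 2663 lower genes (51.8% higher). It turned Cd5 to log2 -0.09. Cd5 was also at -0.04 with wild-type libraries 1 and 2 left out, and at -0.02 without wild-type library 1. The 2 groups differ in more than genotype. Wild-type libraries 1 and 2 hold the female transcript Xist at 80.9 and 63.1 TPM, while wild-type library 3 holds the Y-linked Ddx3y at 54.3 TPM and all homozygous libraries hold it between 107 and 148 TPM. With wild-type libraries 1 and 2 left out 2116 genes were called higher and 742 lower.

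**Figure D1:**
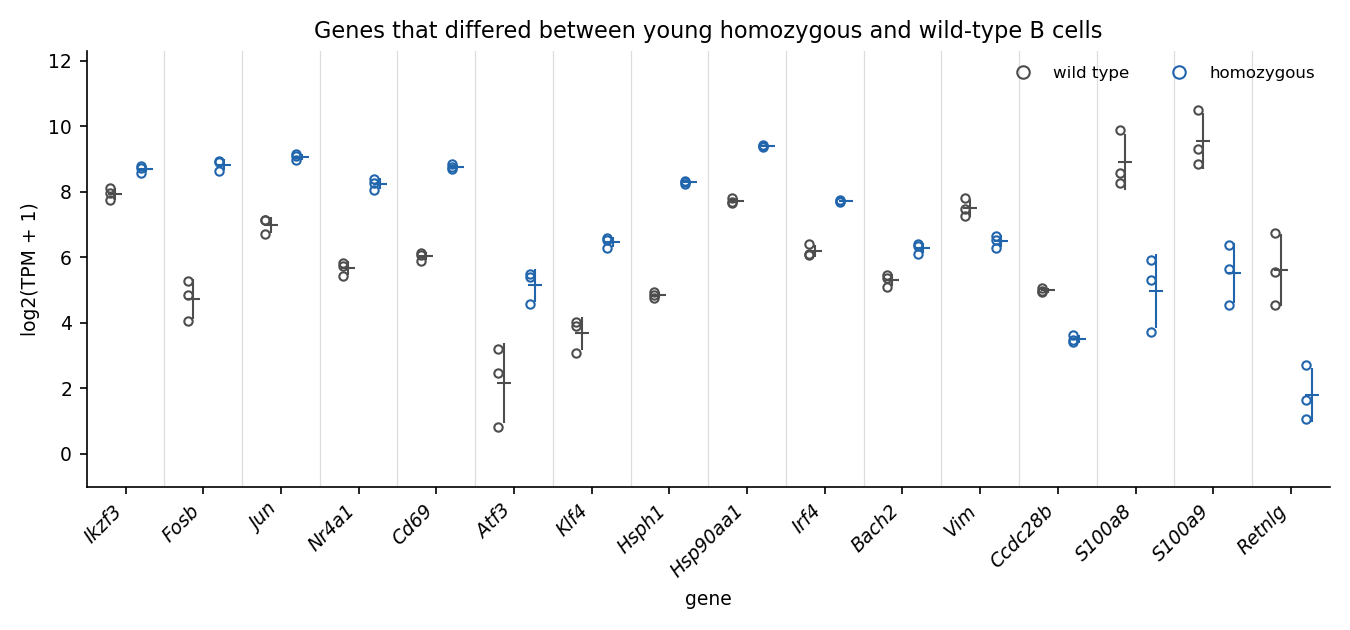
Expression of 16 genes in young wild-type (grey) and homozygous (blue) B cells on a log2(TPM + 1) axis, with a point per library (n = 3 per group) and bars for mean and SD. Fosb is at 27.1 TPM in wild-type and 453 TPM in homozygous B cells on average, and S100a9 at 846 and 51.2 TPM.

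The second comparison sets CLL cells against B cells of aged wild-type mice. 1810046K07Rik (chromosome 9, 51289686 to 51328924) was at 6011 ± 1393 TPM in CLL cells (n = 5) and 12.7 ± 1.99 TPM in wild-type B cells (n = 3), a 433-fold difference (log2 8.76, SE 0.30, adjusted p = 1.08e-31). Hepacam2, a cell adhesion gene, was at 682 ± 97.6 against 127 ± 28.8 TPM (adjusted p = 1.17e-07), and Il5ra, the interleukin-5 receptor, at 219 ± 50.1 against 17.0 ± 11.3 TPM (adjusted p = 1.01e-06). These 3 genes were chosen after their values were seen. Cyp11a1 (chromosome 9, 57998024 to 58027031), the enzyme that begins steroid hormone synthesis, rose to 175 ± 115 TPM from 0.0569 ± 0.0985 TPM (log2 6.91, SE 0.82, adjusted p = 0.00484). Il10, an immunosuppressive cytokine, rose to 99.6 ± 78.3 TPM from 2.399 ± 2.23 TPM (log2 4.87, SE 0.70, adjusted p = 0.00567). Trpm5, a cation channel of taste and tuft cells, Trim40, Fras1 and the keratin Krt18 rose by log2 changes between 3.94 and 4.33 (adjusted p between 7.65e-06 and 0.000464). With at least 20 TPM Trpm5 (adjusted p = 0.0603), Fras1 (0.0695) and Krt18 (0.112) were not called, and after background subtraction none of these 4 was (between 0.0545 and 0.258), although the log2 changes were then still between 3.47 and 4.31. The small nucleolar RNA genes Snord110 and Snord42a, which lie within other genes, rose by 4.08 and 3.90 (adjusted p = 5e-08 and 0.0166).

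Among the decreases were the transcription factors Tox (log2 -4.51, SE 0.79, adjusted p = 0.0174), Tbx21, which encodes T-bet (-3.28, adjusted p = 0.000365), and Stat4 (-3.60, adjusted p = 1.23e-05). The protease Dpp4 (-2.99, adjusted p = 0.000134), the kinase Prkd3 (-3.24, adjusted p = 2.37e-06), Ms4a4c, Tgtp2 and Afap1 (the last 3 between -3.60 and -3.39, adjusted p between 2.87e-05 and 0.0339) fell as well. Bach2 was at 16.7 ± 7.37 against 114 ± 70.4 TPM (log2 -2.51, SE 0.43, adjusted p = 0.000674) and Irf8, a B cell transcription factor, at 110 ± 35.6 against 461 ± 264 TPM (log2 -1.98, SE 0.34, adjusted p = 0.000187). Irf8 was highest in wild-type library 2 (765 TPM), which also held the dendritic cell gene Siglech at 126 TPM, and at 330 and 288 TPM in libraries 1 and 3. The interferon-induced protease Usp18 fell by 1.81 on the log2 scale (adjusted p = 0.0100). Of 25 interferon response genes 2 were lower and 0 higher (the same adjusted over the list alone). Btk, Cd22 and Ptprc, which act at the B cell receptor, fell by 1.04, 1.13 and 1.07 (adjusted p = 0.0488, 0.0291 and 0.0424), while Nfatc1 (log2 1.15) and the inhibitory lectin Siglecg (1.30) rose. Ptprc encodes B220, for which the CLL cells were sorted by flow cytometry, so its change is given as that of a sort marker only. Without wild-type library 1 the calls of Usp18 (adjusted p = 0.0516), Btk (0.203), Cd22 (0.131), Ptprc (0.140) and Nfatc1 (0.0579) ended. Without wild-type library 3 those of Btk (0.243), Cd22 (0.0727), Ptprc (0.197) and Nfatc1 (0.185) ended. Siglecg lost its call without wild-type library 2 (0.0597), Cd22 without CLL library 2 (0.0621), and Nfatc1 (0.0564) and Btk (0.0563) without CLL library 5.

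Of 21 B-1 cell markers 4 were higher and 0 lower (5 and 0 adjusted over the list alone). They were Nid1 (log2 3.04, SE 0.44, adjusted p = 0.000258), Bhlhe41 (2.27, adjusted p = 0.0361), Cd9 (1.503, adjusted p = 0.0381) and Sostdc1 (2.52, adjusted p = 0.0212). Cd9 and Plac8 (1.25, adjusted p = 0.0167) were the 2 marginal zone markers higher of 20 (2 adjusted over the list alone). Plasma cell markers were higher in 4 of 20 cases (5 adjusted over the list alone), with adjusted p between 0.00213 and 0.0231. They were the receptor Tnfrsf13b, which encodes TACI (log2 1.62), Mzb1, listed as 2010001M09Rik (1.51), Prdm1, which encodes Blimp-1 (2.06), and Derl3 (1.54). Of 26 immediate early genes 3 were higher (8 higher and 1 lower adjusted over the list alone), namely Dusp1 (2.41), Egr1 (1.91) and Myc (1.46). Cd274 (log2 2.403, SE 0.39, adjusted p = 0.000146) and Nfkbid (1.53, adjusted p = 0.00683) rose, and the caspase inhibitor Cflar fell (-1.40, adjusted p = 0.0351). Without wild-type library 1 the calls of Bhlhe41 (adjusted p = 0.130), Cd9 (0.167), Derl3 (0.0975), Plac8 (0.0801) and Cflar (0.123) ended. Without wild-type library 3 those of Bhlhe41 (0.174), Myc (0.0660), Plac8 (0.206), Nfkbid (0.174) and Cflar (0.0814) ended.

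Against all genes, whose median log2 change was 0.93, camera called 9 lists lower, with list medians between -0.62 and 0.15. Follicular markers had a median of -0.62 (0 higher and 1 lower of 17, 0 and 4 adjusted over the list alone, adjusted p = 2.32e-07) and interferon response genes of -0.36 (adjusted p = 9.59e-07). B cell receptor signalling had a median of -0.09 (1 and 2 of 29, 2 and 3 adjusted over the list alone) and NF-kB targets of -0.04 (1 and 3 of 31, the same adjusted over the list alone), both at adjusted p = 1.07e-05. Germinal centre markers (median -0.37, 0 and 1 of 16) and antigen presentation (median -0.01, 0 and 0 of 19) were both at adjusted p = 0.000286. Receptor inhibition (0.12), B cell transcription factors (0.15) and homing (0.05) had positive medians while camera pointed down, each at adjusted p = 0.000716. None of the 9 was called with an estimated correlation (adjusted p between 0.0985 and 0.374 with an estimated correlation), and fry called 0 lists (3 at an unadjusted p under 0.05). Without wild-type library 1 camera called 14 lists. With at least 20 TPM, where the median of all genes was -0.04, immediate early genes (adjusted p = 4.83e-05) and B-1 markers (0.00874) were called up and interferon response (0.0413) down. These calls were also lost (adjusted p = 0.606, 0.883 and 0.677 with an estimated correlation).

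In all, 623 genes were called higher and 128 lower of 21202 tested (83.0% higher). Groups did not overlap for 6681 genes (31.5%, against 3.57% by chance). Of the genes called higher 69.0% were under 20 TPM in both groups, and the background rises with them. The median over 1084 olfactory receptor genes was 3.47 ± 3.53 TPM in CLL cells, 9.66 TPM in CLL library 6 alone, and 0.248 ± 0.430 TPM in wild-type B cells. Over genes of at least 20 TPM, 94 were higher and 49 lower (65.7% higher), and after background subtraction 59 and 32 (64.8%). After the subtraction Cyp11a1, Il10, Snord110, Tox, Ms4a4c, Stat4, Afap1, Prkd3, Dpp4, Nid1, Tnfrsf13b, 2010001M09Rik, Irf8, Bach2, Dusp1, Cd274, 1810046K07Rik, Hepacam2 and Il5ra were still called. The other called genes named in this comparison were then not called (adjusted p between 0.0512 and 0.258), with changes in the same direction, or fell under the minimum. The counts of higher and lower genes were 4771 and 341 without CLL library 1, 7744 and 478 without CLL 4, 365 and 114 without CLL 5 and 5324 and 319 without CLL 6. They were 319 and 118 without wild-type 1, 3742 and 516 without wild-type 2 and 265 and 80 without wild-type 3, and 230 genes were lower without CLL 2.

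The third comparison sets CLL cells against non-CLL B cells of mutant mice. 1810046K07Rik was 31.9-fold higher in CLL cells, at 6011 ± 1393 TPM (n = 5) against 213 ± 142 TPM (n = 4; log2 5.00, SE 0.33, adjusted p = 7.44e-08). Hepacam2 was 5.08-fold higher (log2 2.35, SE 0.25, adjusted p = 1.26e-06), and both genes were chosen after their values were seen. Dnase1l3 (chromosome 14, 7965187 to 7994760), a secreted nuclease, was at 8204 ± 1192 against 1336 ± 352 TPM (log2 2.64, SE 0.25, adjusted p = 1.47e-07). Il5ra was at 219 ± 50.1 against 25.2 ± 11.2 TPM (log2 3.14, adjusted p = 1.5e-07), and Il10 at 99.6 ± 78.3 against 11.01 ± 3.72 TPM (adjusted p = 0.00472). Ebi3, a subunit of interleukin-27, was at 103 ± 36.6 against 13.7 ± 4.14 TPM (adjusted p = 4.38e-06). Cyp11a1 (log2 4.40, SE 0.84, adjusted p = 0.0364), the zinc transporter Slc39a4 (2.42, adjusted p = 0.000234) and S1pr3, a sphingosine phosphate receptor (2.49, adjusted p = 0.0345), were also higher. With mouse as a block over mice 2, 4, 5 and 6, the calls of Cyp11a1 (adjusted p = 0.0702) and S1pr3 (0.0556) ended. Cyp11a1 also lost its call without CLL 1, 2 or 5 or any non-CLL library (adjusted p between 0.0576 and 0.0972), and S1pr3 without CLL 1 or non-CLL 4, 5 or 6 (between 0.0682 and 0.0968).

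Genes of other cell types were among the largest decreases. Siglech (chromosome 7, 55768154 to 55779448), a receptor of plasmacytoid dendritic cells, was at 7.80 ± 7.94 TPM in CLL cells and 377 ± 281 TPM in non-CLL B cells (log2 -5.69, SE 0.82, adjusted p = 0.0152). Gzma, a granzyme of NK cells, was at 6.35 ± 3.53 and 175 ± 161 TPM (log2 -4.39, SE 0.65, adjusted p = 0.00794). Lifr, Ctsl, Tcf7l2, Atp1b1, Cxcr3 and Klk1 had log2 changes between -4.97 and -3.89 (adjusted p between 3.4e-06 and 0.0489). NK and dendritic cell markers were lower in 9 of 16 cases (14 adjusted over the list alone), with a median of -2.07 (camera adjusted p = 8.84e-07, and adjusted p = 0.225 with an estimated correlation). The natural killer receptor Ncr1 (-3.39) and the dendritic cell lectin Clec9a (-2.13) were among them. T cell markers such as Cd4 (-3.21) and Cd8b1 (-2.49) were lower in 4 of 15 (10 adjusted over the list alone, camera adjusted p = 0.0045, and adjusted p = 0.428 with an estimated correlation). Precursor B cell genes were lower in 5 of 16 and higher in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0409, and adjusted p = 0.517 with an estimated correlation). Dntt (-3.15), Il7r (-3.14) and Vpreb2 (-2.41) fell and Cd24a (1.76) rose. Among wild-type libraries Dntt and Il7r were highest in library 2 (31.5 and 42.3 TPM), which also held Siglech at 126 TPM. Whether they fell with dendritic cell RNA was not tested. The olfactory receptor background stood with the other-cell genes, at 3.47 ± 3.53 TPM in CLL cells and 8.25 ± 0.854 TPM in non-CLL B cells. Tcf7l2 lost its call without CLL 1, 4 or 5 or any non-CLL library (adjusted p between 0.0645 and 0.118), Atp1b1 without CLL 1, 4 or 5 or non-CLL 2 or 4 (between 0.0517 and 0.0771), and Lifr without CLL 4 or 5 or non-CLL 2 or 4 (between 0.0518 and 0.0603). Clec9a lost it without non-CLL 4 or 6 (0.0627 and 0.0686), Cd24a without CLL 1 or 4 (0.0782 and 0.0563) and Vpreb2 without CLL 1 (0.0509).

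Interferon response genes were lower in 12 of 25 cases and higher in 0 (16 and 0 adjusted over the list alone), with a median log2 change of -1.35 (camera adjusted p = 0.00063, and adjusted p = 0.208 with an estimated correlation). Fry gave adjusted p = 0.00313. Stat2 (-1.41, adjusted p = 0.00406), Mx1 (-1.91), Bst2 (-1.96) and Irf7 (-1.62) were among them. Bst2 and Irf7 are also known from plasmacytoid dendritic cells, whose markers, like the background, were lower in CLL than in non-CLL libraries. With at least 20 TPM 6 of 16 were lower, and the list was then called (adjusted p = 0.0445 with an estimated correlation). Irf8 was at 110 ± 35.6 against 604 ± 141 TPM (log2 -2.48, SE 0.28, adjusted p = 3.08e-06) and Bach2 at 16.7 ± 7.37 against 82.0 ± 33.2 TPM (log2 -2.22, SE 0.35, adjusted p = 0.000375). The chromatin organiser Satb1 (-2.71, adjusted p = 0.000487) and the death receptor Fas (-3.32, adjusted p = 1.83e-05) fell too. Of 26 immediate early genes 3 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.732). Junb (-1.63), Ier2 (-1.38) and the feedback inhibitor Spry2 (-3.82) were lower and Myc (1.86, adjusted p = 0.0131) higher. The chemokine receptors Ccr6 (-2.93) and Ccr9 (-3.51) were among 4 lower and 2 higher of 23 homing genes (8 and 2 adjusted over the list alone, camera adjusted p = 0.565). Lag3 (-3.67) was lower and Cd274 (2.20002) higher among human CLL-associated genes, of which 3 were lower and 1 higher of 24 (8 and 2 adjusted over the list alone, camera adjusted p = 0.723). Among wild-type libraries Lag3, Ccr9, Irf8 and Fas were highest in library 2 (71.6, 19.5, 765 and 147 TPM), which also held Siglech at 126 TPM. Whether their fall follows that of plasmacytoid dendritic cell RNA was not tested.

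Marginal zone markers rose in 6 of 20 cases (7 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.48e-11, and adjusted p = 0.0237 with an estimated correlation). With at least 20 TPM the call was lost (adjusted p = 0.0883 with an estimated correlation), and fry gave adjusted p = 0.0614. Among them were the tetraspanin Cd9, at 307 ± 124 against 62.8 ± 17.1 TPM (log2 2.24, SE 0.29, adjusted p = 2.49e-05), the scavenger receptor Cd36 (1.78, adjusted p = 0.000955), Dtx1 (1.42) and Plac8 (1.21). Against wild-type B cells, only Cd9 and Plac8 of this list were called higher in CLL cells. Cd36 was at 71.0 to 155 TPM in CLL and 90.2 to 346 TPM in wild-type libraries, and Dtx1 at 57.6 to 221 and 20.4 to 126 TPM. B-1 markers rose in 4 of 21 (6 adjusted over the list alone, camera adjusted p = 4.83e-07, and adjusted p = 0.208 with an estimated correlation). They were Cd9, Nid1 (2.66), the phosphatase Ptpn22 (1.26) and Plscr1 (1.13). Genes of B cell receptor signalling rose in 3 of 29 (4 adjusted over the list alone, camera adjusted p = 1.75e-08, and adjusted p = 0.116 with an estimated correlation), namely Nfatc1 (1.46), the kinase Blk (1.00) and Cd81 (0.91). Plasma cell markers rose in 3 of 20 (4 adjusted over the list alone, camera adjusted p = 2.71e-05, and adjusted p = 0.225 with an estimated correlation), namely Tnfrsf13b (1.65), Mzb1, listed as 2010001M09Rik (1.42), and Derl3 (1.24). The calls of Cd81 and Derl3 ended with mouse as a block (adjusted p = 0.0600 and 0.0892). Cd81 also lost its call without any 1 library but CLL 6 and non-CLL 2 (between 0.0669 and 0.118) and Derl3 without any but CLL 6 and non-CLL 6 (between 0.0525 and 0.120). Plscr1 lost it without CLL 1 or 2 or non-CLL 4, 5 or 6 (between 0.0507 and 0.0865), Blk without CLL 4 or non-CLL 4 or 6 (between 0.0708 and 0.119) and Plac8 without non-CLL 4 (0.0713). Against the all-gene median of -0.77 camera also called up cell cycle (adjusted p = 3.38e-08), glycolysis (2.71e-05), Toll-like receptor signalling (0.00103) and, with a negative median, BCL2 family genes (0.0034). No more than 1 member per direction was called in each, and the calls were lost (adjusted p = 0.358, 0.0674, 0.152 and 0.152 with an estimated correlation). Up calls of receptor inhibition (adjusted p = 0.0138), heat shock (0.00163, median -0.06) and antigen presentation (0.0032, median -0.01), and a down call of erythroid markers (0.0347), ended with mouse as a block (adjusted p = 0.0575, 0.0547, 0.0575 and 0.0547). They also ended with an estimated correlation (adjusted p between 0.254 and 0.614 with an estimated correlation).

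In all, 166 genes were called higher and 1121 lower of 22316 tested (12.9% higher), and groups did not overlap for 1937 genes (8.68%, against 1.59% by chance). With mouse as a block 132 genes were higher and 667 lower, of which 109 and 578 were shared with the unblocked calls. TMM rescaling moved the median of all genes from -0.77 to -0.22, gave 310 higher and 163 lower genes (65.5% higher) and turned Ptprc from log2 -0.47 to 0.26. At 20 TPM or more 101 were higher and 166 lower (37.8% higher), and after background subtraction 105 and 141 (42.7%). Of the called genes named in this comparison Blk, Cd81, Mx1, Irf7, Derl3 and Clec9a were then not called (adjusted p between 0.0557 and 0.159), and Vpreb2 fell under the minimum. The log2 changes were then 0.90, 0.77, -2.43, -1.996, 2.36 and -2.98. Without CLL library 6 the counts of higher and lower genes were 382 and 10736. They were 100 and 233 without CLL 1, 100 and 244 without CLL 4 and 103 and 330 without CLL 5. Without non-CLL 2, 4 and 6 they were 96 and 307, 70 and 255, and 83 and 258. The lower count was 620 without CLL 2 and 460 without non-CLL 5.

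**Figure D2:**
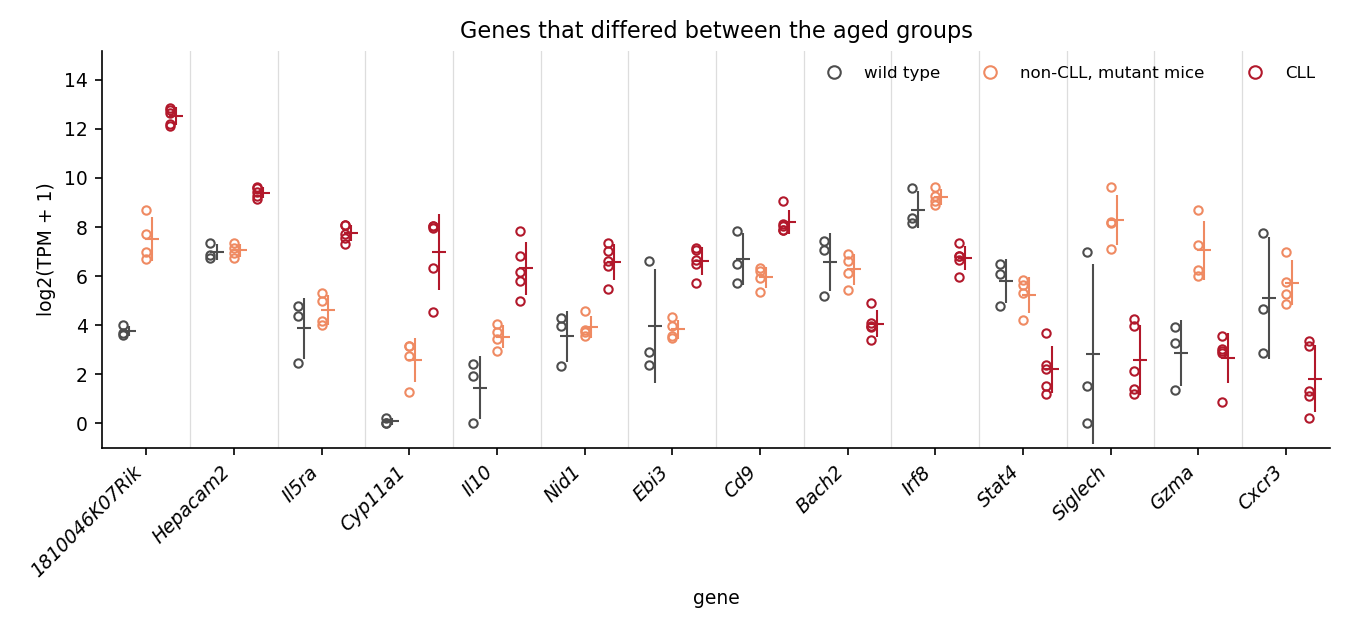
Expression of 14 genes in aged wild-type B cells (grey, n = 3), non-CLL B cells (orange, n = 4) and CLL cells (red, n = 5) on a log2(TPM + 1) axis, with a point per library and bars for mean and SD. 1810046K07Rik averages 12.7, 213 and 6011 TPM in the 3 groups, and Bach2 114, 82.0 and 16.7 TPM.

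The fourth comparison sets non-CLL B cells of aged mutant mice against aged wild-type B cells. Markers of T, NK and stromal cells were higher in the non-CLL libraries. Cd4 was at 35.8 ± 13.0 TPM (n = 4) against 1.81 ± 2.92 TPM (n = 3; log2 4.12, SE 0.63, adjusted p = 0.000202), and the cytotoxic granule gene Nkg7 at 56.6 ± 30.6 against 1.51 ± 1.52 TPM (log2 4.55, SE 0.58, adjusted p = 7.28e-05). The collagen Col1a2 was at 10.4 ± 1.14 against 0.388 ± 0.393 TPM (log2 3.07, SE 0.34, adjusted p = 5.16e-05), and Siglech at 377 ± 281 against 42.6 ± 72.2 TPM (log2 5.44, SE 1.45, adjusted p = 0.0102). T cell markers were higher in 11 of 15 cases (13 adjusted over the list alone), and NK and dendritic cell markers in 11 of 16, stromal markers in 11 of 13 and precursor B cell genes in 11 of 16 (11 each adjusted over the list alone). Human CLL-associated genes were higher in 12 of 24 (12 adjusted over the list alone), myeloid markers in 10 of 22 (9 adjusted over the list alone) and erythroid markers in 6 of 13 (5 adjusted over the list alone). Of all genes tested 12353 of 22150 were called higher, a larger share than in the human CLL-associated, myeloid and erythroid lists. With at least 20 TPM, 0 of 12 human CLL-associated genes and 0 of 5 precursor B cell genes were called higher. The background rose with all of these lists: the olfactory receptor median was 8.25 ± 0.854 TPM against 0.248 ± 0.430 TPM. Wild-type libraries 1 and 3, where it was 0, list 7702 and 8577 genes at 0, while wild-type library 2 lists 829. Of the other named markers only Cd8b1 (log2 3.70) had a mean of at least 20 TPM. Cd3e (3.13), Bcl11b (2.58), Eomes (2.94), Klrb1c (3.37), Gzmb (2.80), Col3a1 (3.18), Pdgfra (2.91) and Acta2 (2.93) lay under it in both groups. Siglech lost its call without wild-type 3 (adjusted p = 0.0544) or any non-CLL library (between 0.0547 and 0.0944).

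Immediate early genes were higher in 16 of 26 cases and lower in 0 (17 and 0 adjusted over the list alone). Their median log2 change of 1.43 lay under that of all genes (camera adjusted p = 0.928), and of the 15 with at least 20 TPM 5 were higher. Some genes that stood well over the background changed as well. Ier2 was at 425 ± 97.3 against 91.2 ± 20.3 TPM (log2 2.21, SE 0.26, adjusted p = 5.19e-05), Dusp1 at 52.4 ± 13.3 against 9.04 ± 9.10 TPM (adjusted p = 0.000926), and Junb, chosen after its values were seen, at 327 ± 80.0 against 62.2 ± 59.2 TPM (adjusted p = 0.00109). The lipid carrier Apoe was at 650 ± 203 against 140 ± 30.4 TPM (log2 2.18, SE 0.28, adjusted p = 7.16e-05). Apoc2, chosen after its values were seen (log2 4.24, adjusted p = 5.16e-05), the lectin Cd209d (4.81, adjusted p = 5.16e-05), Anxa2 (2.64, adjusted p = 0.000336) and Ly6c2 (2.56, adjusted p = 0.000188) rose too. 1810046K07Rik was at 213 ± 142 against 12.7 ± 1.99 TPM (log2 3.76, SE 0.43, adjusted p = 5.29e-05). Sfi1 was at 406 ± 68.9 against 73.0 ± 27.9 TPM and Mir703 had a log2 change of 3.05. These 3 genes were chosen after their values were seen. Mir1912 (56.0 ± 80.2 TPM), Mir720 (27.8 ± 8.57), Mir691 (27.5 ± 13.4) and Mir1947 (26.1 ± 22.9) are listed at 0 in all wild-type libraries, and the brain RNA Bc1 had a log2 change of 4.55 (adjusted p = 0.00166). Dnase1l3 fell, to 1336 ± 352 from 5362 ± 1469 TPM (log2 -1.998, SE 0.27, adjusted p = 8.09e-05), as did Cd36 (-2.23, adjusted p = 0.00169). The ribosomal genes Rps25 (-2.23), Rps4x (-1.87) and Rpl7 (-1.86), and Erh (-2.02), Rab7 (-1.74) and Cerkl (-1.66), were lower with adjusted p between 9.3e-05 and 0.000887. Psmd11 (-1.30) and Ube2v1 (-1.51), lower too, were chosen after their values were seen. Reads of Sfi1, the Mir genes, Bc1 and ribosomal genes can be shared with copies or overlapping genes, so these are uncertain. The kinase Lyn (-0.72, adjusted p = 0.0110) and Ptprc (-0.60, adjusted p = 0.0443) fell, but Ptprc was not called without non-CLL 2, 4 or 6 or wild-type 1 or 3 (adjusted p between 0.0578 and 0.161). After background subtraction Cd209d, Apoc2, Mir703, Junb, Anxa2, Sfi1, Ly6c2, Ier2, Apoe, 1810046K07Rik, Erh, Rps25, Dnase1l3, Ube2v1 and Psmd11 were still called. The other genes named in this comparison were then not called or fell under the minimum, but the log2 changes were then still 5.64 for Siglech, 4.64 for Nkg7, 3.99 for Cd4 and 3.58 for Cd8b1.

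Against the all-gene median of 1.65, camera called stromal markers up (adjusted p = 0.0411) and, among other lists near no change, marginal zone markers and antigen presentation down (both adjusted p = 7.55e-07). B cell receptor signalling had a median of -0.31 (0 higher and 4 lower of 29, 0 and 0 adjusted over the list alone, camera adjusted p = 6.94e-14). No list was called with an estimated correlation (the smallest was adjusted p = 0.0523 with an estimated correlation). With at least 20 TPM, where the median of all genes was 0.04, immediate early genes (5 of 15 higher, adjusted p = 1.96e-07), T cell markers (4 of 7, 2.26e-05) and NK and dendritic cell markers (3 of 8, 6.71e-07) were up. B cell receptor signalling (0.000282) and marginal zone markers (0.0110) were down. Each of these calls was lost (adjusted p = 0.178, 0.178, 0.306, 0.521 and 0.178 with an estimated correlation). Fry called 7 lists up, among them immediate early genes (adjusted p = 0.0072), human CLL-associated genes (0.000514) and interferon response (0.0072). Of the last, 7 were higher and 1 lower of 25 (the same adjusted over the list alone). Fry makes no comparison with other genes, so its calls cannot be told apart from the rise of all genes.

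In all, 12353 genes were called higher and 328 lower of 22150 tested (97.4% higher), and groups did not overlap for 12412 genes (56.0%, against 5.71% by chance). Of the genes called higher 94.2% were under 20 TPM in both groups. At 20 TPM or more 169 were higher and 30 lower (84.9%), and after background subtraction 23 and 5 (82.1%). TMM rescaling moved the median of all genes from 1.65 to 0.94 and gave 10026 higher and 5369 lower genes (65.1% higher). The lower count was 204 without non-CLL 2, 207 without non-CLL 4, 204 without wild-type 1, 561 without wild-type 2 and 142 without wild-type 3.

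**Figure D3:**
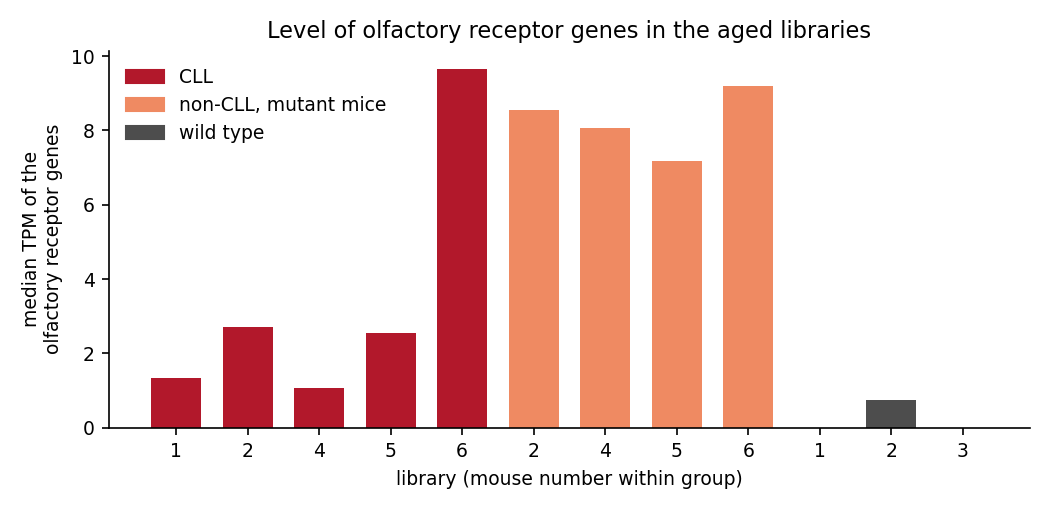
Median TPM of 1084 olfactory receptor genes in each aged library, shown as bars from 0. The non-CLL libraries lie between 7.18 and 9.21 TPM, CLL library 6 at 9.66 TPM, the other CLL libraries between 1.08 and 2.71 TPM and the wild-type libraries between 0 and 0.745 TPM.

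Genes called in young homozygous B cells were followed in the aged table with limma's set tests. Of 468 genes higher by a log2 change of at least 1 in young cells, 213 had at least 20 TPM in the comparison of aged non-CLL B cells with wild-type. Of these 79.3% lay higher in non-CLL B cells, against 53.1% of all genes (camera p = 0.00807 with an estimated correlation), and against no change fry gave 0.00114. In CLL cells 71.9% of 196 lay higher than in wild-type, against 47.5% of all genes (camera p = 0.000774 with an estimated correlation), and against no change fry gave 6.02e-05. The minimum of 20 TPM was chosen after the data were seen. Both limits together were needed for this excess. Without the minimum of 20 TPM, 83.0% of the followed genes lay higher in non-CLL B cells, against 82.8% of all genes, and 77.1% in CLL cells, against 77.2%. Without the limit on the log2 change, 52.5% of the genes of at least 20 TPM lay higher in non-CLL B cells, against 53.1% of all genes, and 44.0% in CLL cells, against 47.5%. With neither, 4129 and 4130 of the 4698 genes higher in young cells were tested in non-CLL B cells and in CLL cells. The shares were then 63.4% in non-CLL B cells and 53.3% in CLL cells, and the p-values of fry were 0.0198 and 0.544. With both limits, genes lower in young cells did not lie lower in the aged groups more often than all genes did. Of 234 such genes with a log2 change of -1 or less, 55 had at least 20 TPM in the comparison of non-CLL B cells, and 29.1% of them lay lower there, against 46.9% of all genes, with a median log2 change of 0.63 (camera p = 0.183 with an estimated correlation). In CLL cells 36.7% of 60 lay lower, against 52.5% of all genes. Of the 1539 genes lower in young cells, 1327 and 1328 were tested in non-CLL B cells and in CLL cells. They lay higher on balance in both aged groups, as did the median of all genes, and the p-values of fry were 0.00296 and 0.0245.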

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

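The tests with other splits of the libraries were set before the data were examined. All other tests of this part were chosen only after the result was seen.

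In 22 of 178 values tested (12.4%), a library of the CLL or non-CLL group stood far from the rest of its group by Dixon's ratio. Chance gives about 5% for normally distributed values, but the ratio was taken on TPM without logarithm. All 22 outlying values lay above the rest of their group, as skewed values would give. The share therefore shows no excess of aberrant libraries. The values tested are those of genes named in the report and of markers per library, a choice narrowed after a first look at them, and they are not independent. CLL library 6 stood apart most often. Its median TPM over the olfactory receptor genes was 9.66, against 1.08 to 2.71 in the other CLL libraries. Also in CLL library 6, Ccr9 was at 13.5 TPM (others 2.04 to 4.27), Cd4 at 9.85 (1.02 to 3.36), Dntt at 12.5 (1.33 to 3.21), Il7r at 16.5 (3.10 to 4.55), Lag3 at 16.6 (2.85 to 6.71), Satb1 at 13.4 (2.36 to 4.84) and Stat4 at 11.8 (1.30 to 4.25). CLL library 2 held Lyz2 at 656 TPM (others 6.20 to 45.9) and Tcf7l2 at 77.2 (2.35 to 18.9). CLL library 1 held Cd274 at 197 TPM (58.2 to 98.2) and Cd9 at 527 (232 to 277), CLL library 4 held Snord110 at 55.2 (41.1 to 43.0), and CLL library 5 held Tgtp2 at 57.6 (6.64 to 15.2). Non-CLL library 6 held Ctsl at 279 TPM (others 87.0 to 91.7), Eomes at 19.9 (8.05 to 8.80), Ly6c2 at 264 (85.2 to 107), Mir1912 at 176 (6.48 to 23.0) and Mir1947 at 59.98 (11.8 to 19.9). Non-CLL library 4 held Ier2 at 569.6 TPM (363 to 397) and Nid1 at 23.0 (10.9 to 12.9), and non-CLL library 2 held Ptpn22 at 259 (153 to 171).

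For 17 of 87 named genes every library moved 1 way in aged non-CLL B cells against wild-type and the opposite way in young homozygous B cells against wild-type. These differences were not tested, since the tables cannot be joined. Neutrophil and macrophage genes lay higher in the aged and lower in the young comparison: S100a9 (log2 2.78 aged, -4.03 young), S100a8 (3.46, -3.94), Retnlg (2.05, -3.80), Saa3 (2.41, -3.07) and Marco (1.91, -1.96). The same held for Siglech (5.44, -1.31), Nkg7 (4.55, -1.67), Cd4 (4.12, -1.24), Klrb1c (3.37, -1.24), Bc1 (4.55, -2.36), Anxa2 (2.64, -1.502), Hopx (1.95, -0.64) and Ifi27l2a (2.31, -1.13). The opposite held for Ptprc (-0.60, 0.58), Cerkl (-1.66, 0.35), Psmd11 (-1.30, 0.42) and Ube2v1 (-1.51, 0.15). In aged non-CLL B cells S100a9, S100a8, Retnlg, Saa3, Marco and Hopx had means of only 5.11 to 18.7 TPM. The olfactory receptor background there was 8.25 TPM, so the aged rise of these genes cannot be told apart from the background.

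The first pattern weighed is the 12353 genes called higher in aged non-CLL B cells, most of them under 20 TPM. A low signal spread over all genes may explain most of it: 91.9% of these genes (11355) gained no more TPM than the 95th percentile of the olfactory receptor genes, 14.3 TPM, and their median gain was 7.68 TPM, against 8.35 TPM for the olfactory receptor genes. Whether the mutation alone raised them cannot be told from the CLL libraries, which carry the same mutation. Of the genes called without non-CLL library 2, 4 or 5, 95.7%, 95.7% and 90.7% lay lower in the CLL than in the non-CLL library of that number. The shares were 81.3%, 78.9% and 76.4% over all genes tested, and 64.7%, 58.2% and 58.3% over genes not called. Olfactory receptor genes gave 98.1%, 98.9% and 91.1%, so the measure follows the background. For number 6, the only homozygous mouse, the share of called genes was 53.6% (49.5% over all genes tested). Its CLL library has a high background too, so genotype and background go together there. What raised the background stays open, and so does a change in the mutant cells for the genes that stood over it, such as Ier2 and Apoe.

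The second pattern is the immediate early and heat shock genes, of which 31 of 37 were called higher in young homozygous B cells. RNA from other cell types is argued against, since 0 of 66 markers of other spleen cells were called higher by limma while 13 were lower (median log2 change -0.95). The sex of the mice stays open: 100% of the 31 genes lay below every homozygous library in wild-type library 3, which is male as the homozygous libraries are, but this is 1 library. Handling of the cells could also raise such genes, and the mean log2 difference of 1.52 for the heat shock list and 1.37 for the immediate early list cannot be told apart from an effect of the mutation, because handling is not given by library. In aged non-CLL B cells, over genes of at least 20 TPM, neither list was called with an estimated correlation (immediate early: median 1.57, 5 of 15 genes called, camera p = 0.0153 but adjusted p = 0.178; heat shock: median 0.13 over 9 genes, camera p = 0.971), so an effect of the mutation in aged cells stays open for both.

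Other splits of the same libraries show how many genes a grouping by chance calls. For non-CLL B cells against wild-type the real grouping called 12681 genes and the highest of the other splits 918, with 1 of 35 splits calling as many. A grouping by chance is therefore argued against. These groups are also parted by the olfactory receptor background (7.18 to 9.21 against 0 to 0.745 TPM), so the count cannot tell genotype from background. For CLL cells against wild-type 2 of 56 splits called as many, the real one included. A wrong split called more genes, so chance is not excluded by this count. The real grouping called 751 genes and the highest other 5358, several times the real count, which points to a structure of the samples: that split parts CLL libraries 2, 5 and 6 from the others, which have the lower olfactory receptor background. For CLL against non-CLL cells 3 of 100 splits drawn called as many, the real one included, and these splits ignore the mice. Wrong splits among them called more genes, so chance is not excluded here either. The real grouping called 1287 genes and the highest other 11763, when CLL library 6 was put with the non-CLL libraries, again a structure that follows the background. The splits that part the 2 libraries of all 4 shared numbers are 16, too few for a share under 0.05 (highest other 748). The young libraries allow 10 splits, too few for a share under 0.05. The real grouping called 6237 genes (1 split), and in the others limma called 0 (at most 589 at an unadjusted p under 0.05).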

How the results depend on the processing

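Chosen only after the data were seen were the minimum of 20 TPM, the background subtraction, both rescalings of the young table and leaving out young wild-type libraries 1 and 2. Depth is unknown, and values under about 20 TPM lie near the background in the non-CLL libraries and CLL library 6. The 95th percentile of the olfactory receptor genes was 14.1 to 27.1 TPM there, and 0 to 6.45 TPM in the other CLL and the wild-type libraries. Every aged comparison holds libraries of high background, which limits every count of called genes there. Rescaling without immunoglobulin genes and the dominance of immunoglobulin variable genes were not run in the aged table, which lists no such genes. Count-based tests and the alternatives to a test by the authors were not run for the young table, whose values are TPM. With young wild-type libraries 1 and 2 left out, the lone wild-type library is assumed to vary as the homozygous ones do.

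Of the genes named other than Ikzf3, direction and side of the threshold were kept in every setting for 51 of 62 in the young comparison, 1 of 42 for CLL cells against wild-type, 31 of 56 for CLL against non-CLL cells and 24 of 42 for non-CLL B cells against wild-type. Not every named gene was followed through the settings: Sostdc1, called in CLL cells against wild-type, was not. Over these genes and all settings, 2889 values were the same, 278 lost their call, 5 gained one and 4 changed sign. The values of these genes that changed sign were Ptprc in CLL against non-CLL cells (0.26 with TMM rescaling) and Cd5 in the young comparison. Cd5 was at -0.0915 with TMM rescaling, at -0.0412 with wild-type libraries 1 and 2 left out, and between -0.0205 and 0.11 without each library. Ikzf3 in CLL cells against wild-type turned to -0.28 with TMM rescaling and -0.16 with the numbers as a block, and ranged from -0.0862 to 0.51 without each library. In non-CLL B cells against wild-type it was at -1.32 and called with TMM rescaling, 0.23 with library weights and 0.0534 with the background subtracted, and ranged from -0.40 to 0.20 without each library. The cause was not tested for these changes.

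For CLL cells against wild-type the counts of higher and lower genes were 8414 and 439 with a pseudocount of 0.1, 182 and 83 with one of 5, and 367 higher without a filter. They were 6409 and 859 with TMM rescaling (median of all genes from 0.93 to 0.70), 6224 and 488 with all 12 libraries, and 10971 and 1328 with library weights. Genes of at least 20 TPM gave 94 and 49, of which 87 and 47 were shared with the main calls, and with the background subtracted 59 and 32. Fewer genes enter these last settings. The counts ranged from 265 to 7744 and from 80 to 516 without each library. With the numbers 1 and 2 as a block limma called 2 and 0 genes (7656 and 275 at an unadjusted p under 0.05), and 40 named genes lost their call (adjusted p between 0.0574 and 0.363). These numbers name different mice. Gene lists called were 9 with camera and 9 to 14 without each library, 3 with at least 20 TPM and 3 with the background subtracted. They were 0 with an estimated correlation and 0 with fry (7 and 3 at an unadjusted p under 0.05). The cause was not tested for the other changes.

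For CLL against non-CLL cells the counts were 74 and 182 with a pseudocount of 0.1, 310 and 163 with TMM rescaling, 3174 lower with all 12 libraries and 499 and 11206 with library weights. Genes of at least 20 TPM gave 101 and 166, and with the background subtracted 105 and 141, with fewer genes tested. Mouse as a block gave 667 lower genes, and the same mice without a block 100 and 233. Without each library the counts ranged from 70 to 382 and from 233 to 10736. Gene lists called were 1 with an estimated correlation, 4 with fry, 7 with at least 20 TPM and 7 with the background subtracted. For non-CLL B cells against wild-type 5369 genes were lower with TMM rescaling and 1011 with library weights. The counts were 169 and 30 with at least 20 TPM and 23 and 5 with the background subtracted, with fewer genes tested, and the lower count ranged from 142 to 561 without each library. Gene lists called were 0 with an estimated correlation (5 at an unadjusted p under 0.05), 7 with fry, 5 with at least 20 TPM and 6 with the background subtracted. For the young comparison the counts were 2859 and 2663 with TMM rescaling, 2116 and 742 with wild-type libraries 1 and 2 left out (fewer libraries), and 944 lower with at least 20 TPM (fewer genes). Gene lists called were 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 6 with at least 20 TPM. With the numbers as a block, which are not shown to pair the young libraries, Saa3 lost its call (adjusted p = 0.0803). The cause was not tested for the changes with TMM rescaling, library weights, pseudocounts and all 12 libraries.

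Genes called in young cells and followed in the aged table depended on the setting too, and these are p-values of fry unless named. For genes higher in young cells, non-CLL B cells gave 0.0198, and 0.528 with at least 20 TPM, 0.616 with young genes of at least 20 TPM and 0.0154 to 0.0551 without each library. The direction turned with camera, which compares with all other genes (4.47e-26), TMM rescaling (4.37e-05) and the background subtracted (0.970). In CLL cells they gave 0.544, and 0.00394 for a log2 change of at least 1. The direction turned with camera (5.2e-19), TMM rescaling (0.128), at least 20 TPM (0.712), the background subtracted (0.598) and young genes of at least 20 TPM (0.780). For genes lower in young cells, non-CLL B cells gave 0.00296, and 0.532 with at least 20 TPM and 0.190 with young genes of at least 20 TPM. The direction turned with camera (8.05e-14), TMM rescaling (0.00871) and the background subtracted (0.850). In CLL cells they gave 0.0245, and 0.0884 for a log2 change of at least 1, 0.160 with at least 20 TPM, 0.354 with the background subtracted and 0.0193 to 0.0874 without each library. The direction turned with camera (1.13e-05) and TMM rescaling (0.740). The cause was not tested, except that camera sets these genes against all others.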

Other observations

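All tests of explanations in this part, with their bounds, were chosen only after the result was seen, and so were the genes named.

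1810046K07Rik, a gene model on chromosome 9, was among the most abundant transcripts of CLL cells. It was at 4399, 6495, 7421, 4664 and 7074 TPM in CLL libraries 1, 2, 4, 5 and 6, which puts it at ranks 16, 10, 9, 11 and 9 of 22781 genes. In non-CLL B cells 2, 4, 5 and 6 it was at 103, 414, 211 and 124 TPM, and in aged wild-type B cells between 11.2 and 14.9 TPM. It was also higher in young homozygous B cells, at 8.10 ± 1.21 TPM (n = 3) against 3.07 ± 0.955 TPM (n = 3; log2 1.18, SE 0.19, adjusted p = 0.00139). In that comparison 4698 of 12219 genes were called higher, and the groups differ in sex as well. Its neighbour Pou2af1, which encodes a B cell coactivator of octamer-binding factors and lies 49607 bases away, was not called in the aged comparisons. Its log2 change was -0.06 (SE 0.31, adjusted p = 0.889) for CLL cells against wild-type and 0.44 (SE 0.32, adjusted p = 0.299) for CLL against non-CLL cells. In young homozygous B cells Pou2af1 rose by 0.57 (SE 0.11, adjusted p = 0.00288). Further genes on that side moved in some comparisons too. In young homozygous B cells Sik2 (0.76, adjusted p = 0.00269) and Ppp2r1b (0.41, adjusted p = 0.00808) were higher, and neither was called in CLL cells against wild-type (log2 -0.99 and -0.36, adjusted p = 0.173 and 0.447). Btg4, with a mean of 3.68 TPM in CLL cells, was lower in CLL than in non-CLL cells (-1.87, adjusted p = 0.0432), and Layn was not called there (-0.72, adjusted p = 0.3002). In non-CLL B cells against wild-type both were higher (log2 3.38 and 2.49, adjusted p = 5.16e-05 and 0.000106), at no more than 15.6 and 7.41 TPM.

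The last pattern weighed is 7 genes called higher in CLL cells that B cells are not known for: Cyp11a1, Trpm5, Trim40, Fras1, Krt18, Hepacam2 and 1810046K07Rik. Several of them are known from tuft cells. The sort for B220 and CD5 selects against such cells, but CLL library 2 held Lyz2 at 656 TPM, so RNA of other cells was not fully removed. RNA of tuft cells as the whole source is argued against by their most typical genes, but a part from such cells is not excluded. The values of 22 other tuft cell markers were set against the 95th percentile of the olfactory receptor genes of the same library. In the 5 CLL libraries 18.2% of these values (20 of 110) lay over it, where the background gives 5%, and 13 markers did so in 0 libraries. Dclk1 (1.14 to 8.998 TPM), Krt8 (0.403 to 5.05) and Pou2f3 (2.02 to 6.85) were among the latter, while Avil (3.08 to 62.7) and Alox5ap (3.98 to 202) did so in 4 libraries, and Hpgds and Gng13 in 3. Against the background, 100% of the 15 values of Cyp11a1, Hepacam2 and 1810046K07Rik lay over that percentile. So did 80% of the 20 values of Trpm5, Trim40, Fras1 and Krt18 (all but 3 of CLL library 5 and 1 of CLL library 6). The smallest gain of the 7 genes over wild-type was 23.8 TPM, against 5.53 TPM for the 95th percentile of the olfactory receptor genes. The 7 genes were picked as called higher in these same libraries, and the first 3 were grouped by keeping their call after background subtraction. These values therefore restate the choice and are no separate test of the background. The minimum of 20 TPM alone ended the calls of Trpm5, Fras1 and Krt18, and with the subtraction added that of Trim40 ended too: the log2 changes of these 4 genes were 3.94 to 4.33 (SE 0.60 to 0.67) at first and 3.47 to 4.31 (SE 0.98 to 1.55) with both, and what widened the SE was not tested.

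Some values belong to single libraries or to 1 table. Aged wild-type library 2 held Ms4a1 at 617 TPM (3610 and 3848 in libraries 1 and 3) and Siglech at 126 TPM. It also held the Y-linked Ddx3y at 17.4 TPM beside the female transcript Xist at 38.1 TPM. CLL library 4 held Xist at 4.104 TPM, against 39.8 to 56.4 TPM in the other CLL libraries, and CLL library 2 held S100a8 at 100 TPM. Gapdh was between 3.96 and 32.1 TPM in the aged and between 577 and 695 TPM in the young libraries, and Ppia between 3.31 and 31.2 and between 881 and 1514 TPM. Actb was between 10830 and 25925 TPM in the aged and between 2686 and 3719 TPM in the young libraries. In 3 chromatin samples, not analysed here, the title and the genotype field disagree.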
